A study of Homo sapiens with 6 samples.

How the data were processed

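Total RNA was taken from HEK293T cells with homozygous miniAID-tagged INTS8, 3 libraries without auxin and 3 libraries with 100 µM auxin for 48 h. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase, depleted of ribosomal RNA and made into libraries with a directional kit. Per the submitters' processing notes, STAR 2.7.3a and DESeq2 were used with the human build hg38 and the fly build dm6, with no role given for either. A fly build can belong to a spike-in, but whether the scale came from one is not given in the sources used here, nor are the counting tool, the annotation and the model formula.

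The data were a table of the authors' own comparison of the 2 groups. Its values were, per the file headers, a mean level per gene, used here as a score because the authors' normalized means were rounded to whole numbers, a linear ratio (fold change), a log2 fold change, and a p-value with an adjusted p-value. Values per library were not used here because the table gives only the comparison. The planned test of counts or normalized values per library was therefore replaced by the authors' deposited adjusted p at 0.05, as laid down for this case before the data were examined. Depth per library is unknown, so no interval or detection limit from read counts is given. The mean levels of the 14538 genes sum to 36952771, of which RN7SK makes up 1.63%. The header does not name the numerator, and positive values were read as higher with auxin by convention, which nothing in the table checks. A further column of log2 expression values, which names no group, was not used here.

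The table was checked before use. The deposited adjusted p matched Benjamini-Hochberg adjustment over the 14479 genes with a p below 1, with a largest relative difference of 0.00771, and 59 genes had a p of 1. There were 56 genes listed with a p of 0, and 165 with a mean level rounded to 0. The authors' own mark of changed genes equalled an adjusted p under 0.001 with a change of at least 2-fold in 1189 of 1189 marked genes. Of the gene identifiers, 14523 were found in GENCODE 29, and 2415 had identical coordinates there. Printed coordinates are those of the authors' table, in hg38, and GENCODE 29 was used for overlapping genes and exon numbers.

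From the deposited values several quantities were computed. A standard error was derived as the log2 fold change over the normal quantile of its p-value, which assumes a two-sided Wald test that the notes do not state, and for genes with a p of 0 it is an upper limit. Its median was 0.0834 for genes with a mean level of at least 100 and 0.301 for levels from 10 to 99, so small changes in the latter were less detectable. Levels per group were derived from the mean level and the fold change, assuming groups of equal size. Gene lists were compared by the percentile of the median log2 fold change among 10000 random lists of the same size matched on mean level in 20 bins, with the two-sided share adjusted by Benjamini-Hochberg over 23 lists. Shares of higher genes have 95% Clopper-Pearson intervals.

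The 24 gene lists, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were INTS8, the 6 largest rises and 6 largest falls past adjusted p 0.05 with a mean level of at least 100, ATF4, DDIT3, ASNS and TRIB3, and per list the 2 members with the largest absolute log2 fold change past 0.05 and a mean level of at least 20. A gene that this rule takes is not reported here. A list of DUX4 targets was written after the values were seen. The lists share few genes, namely CARS1, GDF15, SESN2, DDX58, EIF2AK2, IFIH1 and BTG2. The alternatives were an adjusted p of 0.01, fold limits of 1.5 and 2, mean levels of at least 10 and 100, centring, in which the median log2 fold change of genes with a mean level of at least 100 (-0.0302) was subtracted from every gene, a Wald test against a fold of 1.5, adjustment over every gene, protein-coding genes alone, list members with a mean level of at least 100, and random lists without matching. Only the INTS8 comparison at 48 h was present in the table, so no further comparisons were made.

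The computations were tested on simulated data for the comparison of auxin and no auxin groups over 14479 genes, of which 200 were changed. After centring, 100% of genes changed by 1 on the log2 scale and 88% of those changed by 0.5 were recovered, and a shift of -0.3 was recovered as -0.3. Of 100 lists without change 4 were called, and of 20 raised lists 20 were called. The changed genes were raised and lowered in equal numbers, all at a mean level of at least 100. Noise was drawn from the derived standard errors, independently per gene. The simulation therefore checks the computations, and does not cover data with many changed genes, unequal directions or lists whose members vary together. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.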

Results

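RNA-seq was analysed from INTS8-AID HEK293T cells, an embryonic kidney line with a homozygous miniAID tag on INTS8. The tag is an auxin-inducible degron, which lets the plant hormone auxin direct destruction of the tagged protein. INTS8 is a subunit of Integrator, a complex that cleaves nascent RNA and ends transcription by RNA polymerase II at small nuclear RNA genes and early in many coding genes. There were 3 libraries of cells given 100 µM auxin for 48 h and 3 libraries of cells without auxin. The comparison addressed how RNA levels differed after auxin in INTS8-AID cells, including genes of the integrated stress response and of double-stranded RNA sensing. All values came from the authors' deposited table of this comparison, which listed 14538 genes, of which 12824 were protein-coding. It holds no values per library, so depth per library and spread between replicates are unknown here, and its header does not name the numerator of the fold changes. They were read as auxin over no auxin by the usual convention of treated over untreated. No value in the table checks this reading, and if it is wrong every rise given is a fall and every fall a rise. No label says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries.

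The mRNA of INTS8 was higher with auxin, at 1.28-fold (log2 fold change 0.35, adjusted p 1.33e-07) in the authors' deposited table. INTS8 lies on chromosome 8 from 94823287 to 94881746 in hg38, on the plus strand, and overlaps CCNE2 on the other strand. Because the tag acts on the protein, the mRNA does not show whether INTS8 protein was lost, and it gives no check of the labels. Among 20 measured Integrator subunits and associated proteins, 9 rose and 5 fell. The authors' deposited table gave 3.66-fold for INTS6L and 2.39-fold for NABP1, a single-stranded DNA binding protein that joins the complex. The fallers were INTS11, the RNA endonuclease of the complex, INTS10, INTS9, INTS3 and INTS1, at 0.757, 0.774, 0.799, 0.810 and 0.820-fold in the authors' deposited table, and these 5 were named after their values were seen. The median log2 fold change of the list was 0.15, at percentile 98.6 of random lists matched on mean level (adjusted share 0.0662), and the counts were 9 and 5 when adjusted over the list alone.

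Auxin treatment was followed by changes in both directions, and the large ones were mostly rises. At an adjusted p of 0.05 in the authors' deposited table, 4042 genes were higher, 4203 were lower and 6293 did not pass. Higher genes made up 49.02% of those past the threshold (95% Clopper-Pearson interval 47.94 to 50.11), or 50.98% if the fold changes run the other way. At a change of at least 2-fold, 1145 genes rose and 198 fell, so that 85.26% were rises (83.25 to 87.11), or 14.74% if the fold changes run the other way. At least 4-fold rises numbered 383 against 1 fall, and 127 genes rose at least 10-fold against 0 falls. The 1 fall was ARRDC3-AS1, an antisense RNA at 0.2497-fold in the authors' deposited table, named after its value was seen. The median log2 fold change was 0.00 over all listed genes. The intervals treat genes as independent, which they are not.

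**Figure D1:**
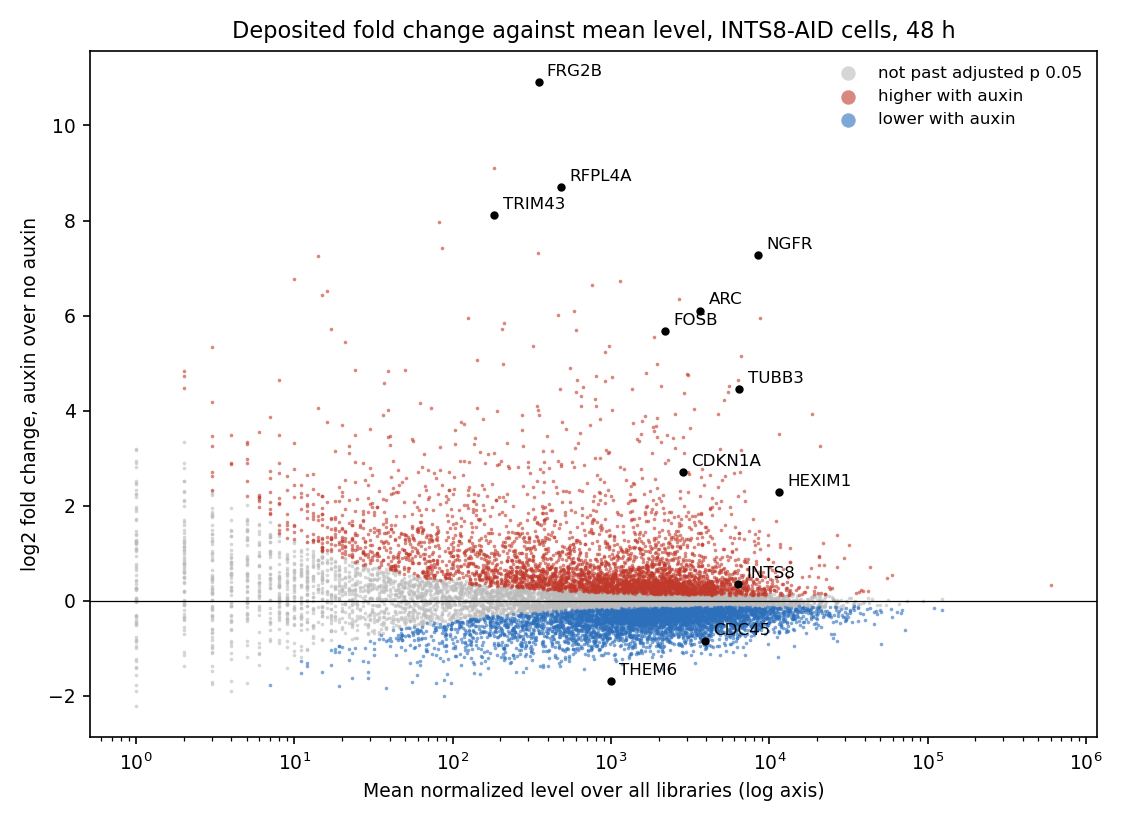
Each point is a gene with a mean level of at least 1, with its mean normalized level over all libraries on the x axis (log axis) and its log2 fold change, auxin over no auxin, on the y axis; red and blue mark genes higher and lower at adjusted p 0.05 and grey the rest. Points above the zero line reach 10.92 for FRG2B, and the lowest labelled gene is THEM6 at -1.68.

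**Figure D2:**
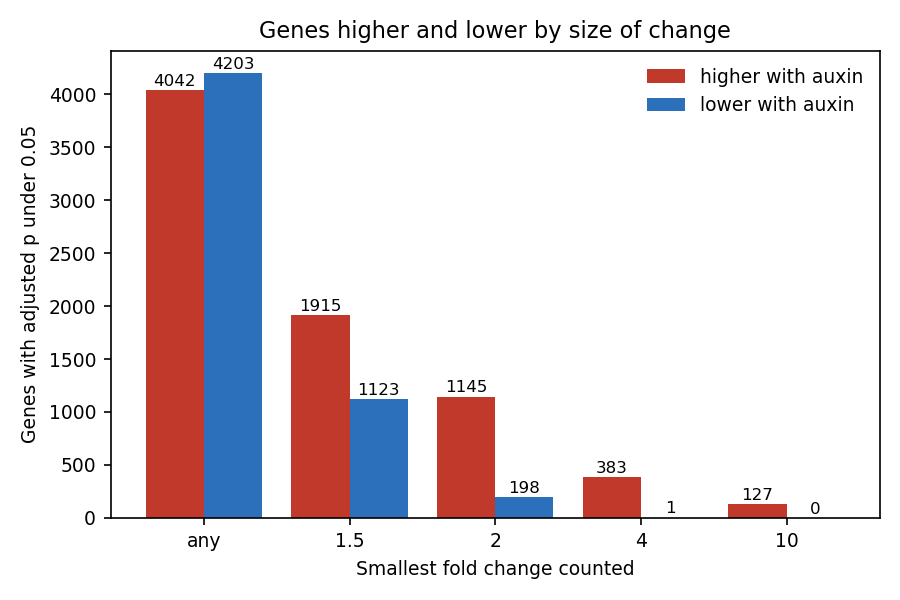
Bars give the number of genes higher (red) and lower (blue) with auxin at adjusted p 0.05, by the smallest fold change counted on the x axis. The counts are 4042 and 4203 with no fold limit, and 1145 and 198 at 2-fold.

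Gene types differed in their counts of rises and falls. Of 1384 long noncoding RNAs, 373 rose and 86 fell, and of 110 small nuclear RNA genes, 31 rose and 0 fell. Among protein-coding genes 3594 rose and 4096 fell, with 905 rises and 184 falls of at least 2-fold. A mean level of at least 20 was reached by 769 of the long noncoding RNAs, 45 of the small nuclear RNA genes and 12504 of the protein-coding genes. The counts thus compare types of unlike level. Among genes of at least that level the median log2 fold changes were 0.29, 0.61 and -0.03, in the same order. The difference between gene types was not tested.

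Among the 6 largest rises of genes with a mean level of at least 100, FRG2B, FRG2C, RFPL4A, TRIM43 and PRR20G had derived levels without auxin of 0.360, 0.658, 2.32, 1.32 and 4.31. FRG2B (chromosome 10, 133623895 to 133626795) had a mean level of 348 and a log2 fold change of 10.92 in the authors' deposited table, and FRG2C (chromosome 3, 75664328 to 75667220) had 181 and 9.10. RFPL4A was 417-fold higher, TRIM43 276-fold and PRR20G 159-fold in the authors' deposited table. Folds against levels so close to zero are imprecise. These genes have near-identical copies, so which copy the reads came from is uncertain. NGFR, the low-affinity nerve growth factor receptor, was 155-fold higher at a mean level of 8417 in the authors' deposited table, from a derived level without auxin of 108, and overlaps other annotated genes. The largest falls among genes with a mean level of at least 100 in the authors' deposited table were THEM6 at 0.311, C16orf74 at 0.346, COL4A3, a basement membrane collagen chain, at 0.348, RIN2 at 0.355, CRYL1 at 0.357 and the homeobox gene CUX2 at 0.369. For these 6 the adjusted p ran from 3.54e-56 for THEM6 to 1.42e-16 for C16orf74 in the authors' deposited table.

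Immediate early genes, which respond within minutes to growth factors and stress, rose together. Of 37 measured members 32 rose, 28 of them at least 2-fold, and 3 fell. ARC, a regulator of synaptic receptors, was 68.8-fold higher and the AP-1 subunit FOSB 50.8-fold in the authors' deposited table. The fallers ID3, MYC and KLF6, named after their values were seen, were at 0.851, 0.867 and 0.898-fold in the authors' deposited table. The list's median log2 fold change of 2.09 was at percentile 100 of the random lists (adjusted share 9.2e-04), and adjusted over the list alone the counts were 32 and 3. The share cannot fall below 2.0e-04 before adjustment with 10000 random lists.

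Members of the ATF4 and integrated stress response list split evenly with no fold limit, with 17 of 41 higher and 17 lower. At a change of at least 2-fold 7 rose and 1 fell. The stress-induced transcription factors ATF3 and DDIT3 (CHOP) were 6.82-fold and 3.71-fold higher in the authors' deposited table. ATF4 mRNA was at 0.840-fold (adjusted p 9.67e-04) and TRIB3, a target of ATF4 and CHOP, at 0.810-fold (adjusted p 1.18e-03) in the authors' deposited table. ASNS, which makes asparagine, stood at 1.05-fold and did not pass (adjusted p 0.535) in the authors' deposited table. The median log2 fold change was -0.14 and the mean 0.21, which differ in sign, and the median was at percentile 4.30 of the random lists (adjusted share 0.153). Adjusted over the list alone the counts were 17 and 17. DDIT3 overlaps MARS in the annotation, and ATF4 is controlled largely at translation, which RNA levels do not measure.

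Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, had 11 of 20 members lower and 2 higher. VARS1 and FARSB were at 0.678 and 0.683-fold in the authors' deposited table. The higher members HARS1 and TARS1, named after their values were seen, were at 1.16 and 1.10-fold in the authors' deposited table. The median of -0.17 was at percentile 12.6 (adjusted share 0.364), and the counts adjusted over the list alone were 2 and 11. The list of endoplasmic reticulum chaperones and other targets of ATF6 and XBP1 had 14 of 20 members higher and 2 lower. HERPUD1 was 1.78-fold and DNAJB9 1.72-fold higher in the authors' deposited table. EDEM1 and PDIA6, named after their values were seen, were the lower members at 0.717 and 0.868-fold in the authors' deposited table. The median of 0.46 was at percentile 100 (adjusted share 9.2e-04), with counts of 14 and 2 adjusted over the list alone.

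Genes of double-stranded RNA binding and the eIF2 alpha kinases moved both ways, 9 higher and 10 lower of 28. DHX58 (LGP2), a RIG-I-like receptor, was 6.53-fold higher and EIF2AK3 (PERK), the kinase of the endoplasmic reticulum, 1.62-fold higher in the authors' deposited table. The kinases EIF2AK4 (GCN2) and EIF2AK2 (PKR) were at 0.694 and 0.751-fold in the authors' deposited table, named after their values were seen. Their median of -0.05 was at percentile 51.5 (adjusted share 0.970), and adjusted over the list alone the counts were 9 and 10. Among 29 interferon-stimulated genes 15 rose and 5 fell. IRF7 was 4.02-fold and ISG20 3.91-fold higher, in the authors' deposited table. The lower members OAS3, USP18, EIF2AK2, HERC6 and LGALS3BP were named after their values were seen. The median of 0.33 was at percentile 98.96 (adjusted share 0.0542), with 15 and 5 adjusted over the list alone. Of 16 NF-kB targets 10 rose and 2 fell, the fallers being BCL3 and NFKB1, named after their values were seen. IER3 was 6.75-fold and NFKBIZ 3.77-fold higher in the authors' deposited table. Their median of 0.40 was at percentile 98.2 (adjusted share 0.0778), and adjusted over the list alone the counts were 10 and 2.

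Targets of p53 rose in 17 of 27 cases and fell in 9. PLK3 was 7.74-fold higher and CDKN1A, the cyclin-dependent kinase inhibitor p21, 6.54-fold higher in the authors' deposited table. The lower members included SPATA18 at 0.454 and BBC3 (PUMA), a mediator of apoptosis, at 0.478-fold in the authors' deposited table, named after their values were seen. The median of 0.36 was at percentile 100 (adjusted share 9.2e-04), and adjusted over the list alone the counts were 17 and 9. HEK293T cells carry SV40 large T antigen, which binds p53.

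Genes of the G1/S transition and DNA replication fell, with 26 of 34 lower and 5 higher. CDC45, part of the replicative helicase, was at 0.558-fold in the authors' deposited table. Among the higher members was CCNE1 (cyclin E1) at 1.75-fold in the authors' deposited table. The other 4, CCNE2, CLSPN, GINS4 and RRM2, were named after their values were seen. The median of -0.34 was at percentile 0 of the random lists (adjusted share 9.2e-04), and adjusted over the list alone 5 rose and 28 fell. G2/M genes had 12 of 27 higher and 5 lower. The kinase NEK2 was 2.79-fold and the kinesin CENPE 1.85-fold higher in the authors' deposited table, while HMMR, BUB1B, TOP2A, CDC20 and BIRC5 fell, named after their values were seen. The median of 0.12 was at percentile 99.6 (adjusted share 0.0256), with 12 and 5 adjusted over the list alone, but against random lists not matched on mean level the adjusted share was 0.355.

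Small nuclear RNA genes transcribed by RNA polymerase II rose in 9 of 18 cases, and 0 fell. The U1 genes RNU1-2 (chromosome 1, 16895980 to 16896143) and RNU1-1 (chromosome 1, 16514122 to 16514285) were 5.01-fold and 3.85-fold higher in the authors' deposited table, and reads cannot be assigned with certainty among U1 copies. Their mean levels were only 95 and 124. RNU1-2 also overlaps CROCC on the same strand, so its reads may include those of CROCC. Whether mature U1 RNA rose is not shown by these values. The median of 0.35 was at percentile 96.7 (adjusted share 0.129), with 9 and 0 adjusted over the list alone. Replication-dependent histone genes went both ways, 15 higher and 10 lower of 48. H2BC8 was at 1.60-fold and H2AC15 at 0.612-fold in the authors' deposited table. The histone median of -0.05 was at percentile 65.8 (adjusted share 0.867), with 15 and 10 adjusted over the list alone.

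Factors of pausing and premature termination included large rises of HEXIM1, the inhibitor of the elongation kinase P-TEFb, at 4.90-fold, and of CTR9, a PAF1 complex subunit, at 2.32-fold in the authors' deposited table. SYMPK and CDK9, the kinase of P-TEFb, were at 0.683 and 0.698-fold in the authors' deposited table, named after their values were seen. Of 29 members 8 rose and 6 fell, also when adjusted over the list alone, and the median of 0.02 was at percentile 89.8 (adjusted share 0.312). The RNA exosome and its cofactors had 9 of 19 lower and 1 higher, ZCCHC8, named after its value was seen. EXOSC4 and EXOSC5 were at 0.719 and 0.723-fold in the authors' deposited table. The exosome median of -0.18 was at percentile 7.09 (adjusted share 0.233), and adjusted over the list alone the counts were 1 and 9.

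Aryl hydrocarbon receptor targets rose, with 5 of 6 members higher and 0 lower. CYP1B1 was 4.50-fold and ALDH3A1 3.11-fold higher in the authors' deposited table. CYP1A1, NQO1 and TIPARP rose as well, at 2.18, 1.55 and 1.38-fold in the authors' deposited table, and were named after their values were seen. The median of 0.88 was at percentile 99.5 (adjusted share 0.0322), with 5 and 0 adjusted over the list alone. The series as used here held 0 libraries of auxin-treated cells without the tag.

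Cytosolic ribosomal protein genes fell in 25 of 84 cases and rose in 5, or 24 and 3 when adjusted over the list alone. The rises included RPL3L, a muscle paralog of RPL3, at 8.72-fold in the authors' deposited table. RPL7L1, a paralog of RPL7, was at 0.702-fold in the authors' deposited table. The other 4 higher members, RPS27L, RPL26L1, RPLP1 and RPS21, were named after their values were seen. The median of -0.09 was at percentile 57.3 (adjusted share 0.918). Nuclear-encoded respiratory chain subunits fell in 24 of 75 cases and rose in 4, or 23 and 4 adjusted over the list alone. NDUFA10 of complex I was at 0.664-fold and ATP5PD of the ATP synthase at 0.677-fold in the authors' deposited table. The higher members NDUFA4, COX6C, NDUFB1 and COX6B1 were named after their values were seen, and the median of -0.06 was at percentile 43.8 (adjusted share 0.918). The list of mitochondrially encoded mRNAs had 0 measured members.

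Cholesterol synthesis genes had 7 of 24 higher and 8 lower, also when adjusted over the list alone. The transcription factor SREBF2 was at 0.596-fold in the authors' deposited table. IDI1, an enzyme of isoprenoid synthesis, was at 1.66-fold in the authors' deposited table, named after its value was seen. Their median of -0.02 was at percentile 61.0 (adjusted share 0.898). Heat shock genes had 7 of 18 lower and 3 higher, also when adjusted over the list alone, with BAG3 at 1.67-fold and DNAJB1 at 1.51-fold in the authors' deposited table. DEDD2 was the other higher member and HSPE1, a mitochondrial chaperonin, a lower one at 0.828-fold in the authors' deposited table, both named after their values were seen, and the median of -0.04 was at percentile 64.2 (adjusted share 0.867).

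Markers of neurons, of blood cells and of epithelial and fibroblast cells were also measured. Of 17 neuronal markers 10 were listed, and 9 rose, with 0 lower. TUBB3, a neuronal tubulin, was 22.0-fold higher and NEFM, a neurofilament chain, 10.8-fold higher in the authors' deposited table, from derived levels without auxin of 561 and 478. These rises were in the same comparison as those of immediate early genes and p53 targets. The neuronal median of 1.69 was at percentile 100 (adjusted share 9.2e-04), with 9 and 0 adjusted over the list alone. Of 15 blood cell markers 6 were listed and 4 rose, with 0 lower. CD68 was 10.03-fold and HBA1 5.01-fold higher in the authors' deposited table, and HBA1 shares reads with HBA2. CORO1A and HBA2 also rose, named after their values were seen. The blood cell median of 2.21 was at percentile 99.97 (adjusted share 0.00307), with 4 and 0 adjusted over the list alone. The rises of HBA1 and HBA2 are not separate, and CD68 overlaps a gene on the same strand. Only 3 of the 6 listed members had a mean level of at least 100, and 2 of these rose. Of 15 epithelial and fibroblast markers 5 were listed and 2 rose, KRT8 at 1.77-fold and KRT18 at 1.24-fold in the authors' deposited table, with a median of 0.09 at percentile 68.9 (adjusted share 0.843) and counts of 2 and 0 adjusted over the list alone.

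**Figure D3:**
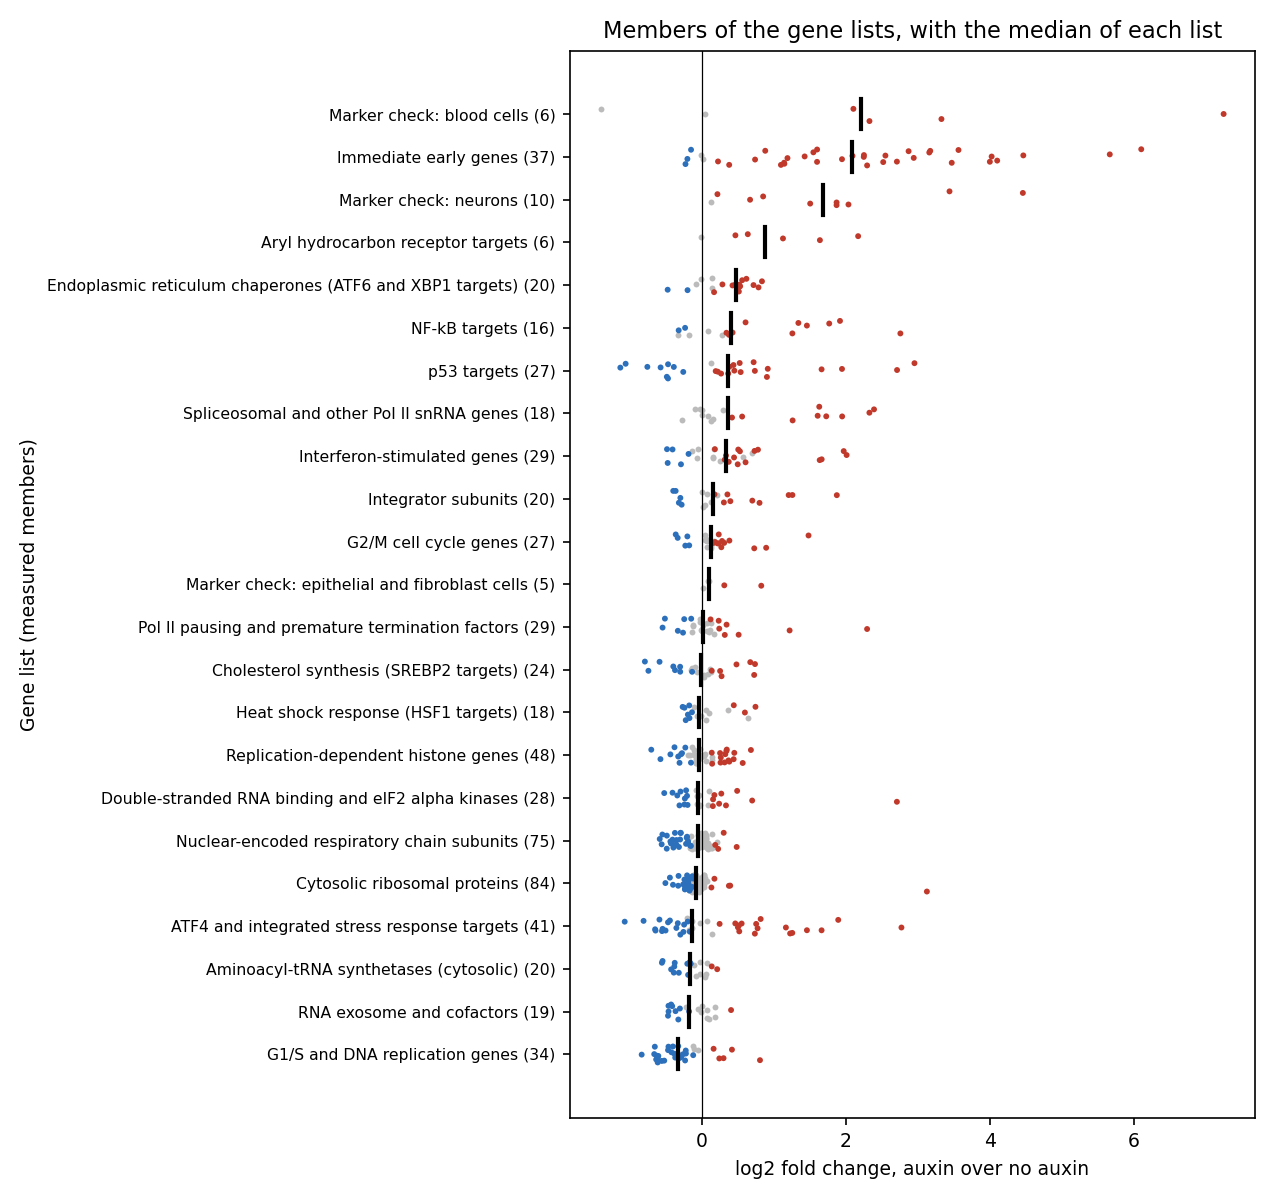
Each point is a measured member of a gene list, with its log2 fold change, auxin over no auxin, on the x axis; lists are ordered by their median, drawn as a black bar, red and blue points passed adjusted p 0.05 and grey points did not. The medians run from -0.34 for G1/S and DNA replication genes to 2.21 for blood cell markers, with immediate early genes at 2.09.

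Of 23 lists compared with random lists, 7 lay above and 1 below at an adjusted share of 0.05. These shares describe the deposited fold changes and are no test across replicates, and they are too small where members of a list vary together. Of 62 named genes, 27 overlap a gene on the other strand and 16 a gene on the same strand in GENCODE 29, and whether the authors' counting used strand is not given in the sources used here.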

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

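The settings with a mean level of at least 1000, the authors' own mark and the ribosomal list without paralog names were chosen after seeing the data. No paired analysis was possible because the authors' deposited table gives only the comparison of the groups. For the same reason another normalization or count test, other count filters and pseudocounts, leaving out each library, an estimated correlation and other splits of the libraries were not run. Depth per library is unknown and limits genes of low level most.

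Of 4042 higher and 4203 lower genes (49.02% higher), 1915 and 1123 (63.03%) passed with a fold over 1.5, 1145 and 198 (85.26%) with a fold over 2, 1047 and 322 (76.48%) in the Wald test against a fold of 1.5, and 1006 and 183 (84.61%) by the authors' own mark. These settings by construction ask for larger changes. The share was 46.15% at a mean level of at least 100, 46.77% in protein-coding genes and 53.48% after centring, and 41.99% at a mean level of at least 1000, where 2044 genes were higher. With fewer genes tested, 2-fold rises numbered 735 at a mean level of at least 100, and 2-fold rises and falls 324 and 45 at 1000. The median log2 fold change of all genes was 0.0302 after centring on the median of genes with a mean level of at least 100, and it was -0.0302 at a mean level of at least 100 and -0.0509 at 1000. An adjusted p of 0.01, a mean level of at least 10 and adjustment over every gene left these counts within 1.5 times. Every share of higher genes here rests on reading the fold changes as auxin over no auxin. On the other reading it would be the share of lower genes.

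NF-kB targets passed with members of a mean level of at least 100 (median 0.51, adjusted share 0.0252). Against random lists without matching, NF-kB targets (0.40), interferon-stimulated genes (0.33) and small nuclear RNA genes (0.35) passed and G2/M genes (0.12) did not; the cause was not tested. INTS8 and the other named genes kept their direction and their side of the threshold after centring. Counts of list members moved by over 1.5 times in 6 cases at an adjusted p of 0.01, in 1 after centring and in 1 with members of a mean level of at least 100. Blood cell markers and epithelial and fibroblast markers had too few members of that level for a median. Without paralog names, the ribosomal list had a median of -0.11.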

Other observations

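The tests on the aryl hydrocarbon receptor targets and on the copies of FRG2, TRIM43 and RFPL4, the splits of single-exon genes, the exon classes and the scan of gene families were chosen after the values were seen. The scan took in 219 families of protein-coding genes sharing a symbol stem and with at least 8 members. Protocadherins with the stem PCDH, cell adhesion proteins of the nervous system, were over-represented among 2-fold rises. Protocadherin genes with another stem were not counted with them. Of 8 members with the stem PCDH 5 rose at least 2-fold where 0.565 were expected (hypergeometric p 8.15e-05, adjusted p 0.0357 over both directions). PCDH19 was 35.3-fold, PCDH8 29.8-fold, PCDH9 9.61-fold, PCDH10 9.002-fold and PCDH18 2.04-fold higher in the authors' deposited table. The families over-represented among lower genes were DENND, regulators of Rab GTPases, with 12 of 15 lower where 4.80 were expected, and MCM, which includes the replicative helicase, with 9 of 10 lower where 3.20 were expected (adjusted p 0.0362 for both). DENND3 was at 0.497-fold, DENND2C was higher at 1.52-fold (adjusted p 1.22e-12) and MCM3 at 0.634-fold in the authors' deposited table. The stem MCM also takes in MCM3AP, which is not a helicase subunit, and genes are not independent replicates. MCM2, MCM3, MCM4, MCM5, MCM6, MCM7 and MCM10 are also in the list of G1/S and DNA replication genes. The MCM result is thus not separate from the fall of that list.

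More genes rose than fell by at least 2-fold, 1145 against 198. The ratio of rises to falls was 7.16 after centring, so relative to the median gene large rises still outnumbered large falls. Centring subtracted only -0.0302 and could hardly move the ratio, and it takes the median gene as unchanged. Whether a shift of the common scale between the groups contributed therefore stays open. The ratio of 7.20 at a mean level of at least 1000 argues against low read numbers over all libraries as the whole cause. That mean takes in both groups, so a gene that rose from a low level can pass. FOSB, for example, had a mean level of 2198 and a derived level without auxin of 84.8. Genes were not split by their level without auxin, so a part played by low starting levels stays open. Only 7 of the 1145 rises had a listed same-strand upstream neighbour within 10 kb that rose 2-fold. This argues against transcription running in from such neighbours as the cause of most of the rises. Without genes that had such a neighbour the ratio was 5.84. Unlisted or overlapping neighbours, neighbours with smaller rises and longer distances stay open. The biological difference named by the design, auxin acting on tagged INTS8, cannot be separated from auxin itself.

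Aryl hydrocarbon receptor targets rose, and the natural auxin is an indole, a class that includes ligands of this receptor. The compound used is not given in the sources used here. A candidate explanation is that auxin itself acted on the receptor, apart from loss of INTS8. This cannot be told apart from an effect of INTS8 loss, because the series as used here held 0 auxin-treated libraries of untagged cells. The list's position at percentile 99.45 of random lists matched on mean level (adjusted share 0.0322 over 23 lists) is above what genes of this expression level gave. It is the value that drew attention to the list, so it is no independent test.

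Copies of FRG2, TRIM43 and RFPL4 rose from near zero. Reads moving between listed copies would leave the family sums level, but the smallest derived rise of a family sum was 231.6-fold, with the sum without auxin at 2.31 for the TRIM43 pair. Every listed copy of these families was higher, so the sums had to rise and are no separate test. Reads from copies that are not listed were not examined. These genes are known targets of DUX4, a transcription factor of the early embryo, and a hypothesis is that a wider set of its targets may have risen. Of 76 targets on a DUX4 list 16 were in the table, and 60 were not analysed here. The other 9 of the 16 had a median log2 fold change of 0.44 at percentile 98.28 of matched random lists, with 6 higher and 1 lower. Since that list was written after the values were seen and includes PRR20G, one of the largest rises, the percentile cannot decide it.

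A hypothesis written before the test was that coding genes with a single exon rose more often. Of 296 such genes 18.2% rose at least 2-fold, against 6.80% of 12478 other coding genes, a ratio of shares of 2.68 (exact Fisher p 7.51e-11). The odds ratio was 2.12 in the lowest, 3.56 in the middle and 3.92 in the highest of 3 equal classes of mean level, and 3.61 without histone genes. The share rising 2-fold was 12.5% with 2 to 4 exons, 6.92% with 5 to 10 and 4.65% with over 10. Shorter genes and immediate early genes are among those with few exons, and these were not separated.

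A further hypothesis was that transcription running in from a rising upstream neighbour raised genes downstream. Of 118 genes within 10 kb downstream of a rising gene on the same strand 6 rose at least 2-fold. Of 272 with a rising gene on the other strand as close upstream, 25 did (odds ratio 0.53, exact Fisher p 0.222). Those other-strand neighbours were transcribed away from the gene, and whether such pairs rise together for another reason was not tested. The 8 genes with rising neighbours on both strands were left out, 1 of which rose, and 7.87% of genes with neither neighbour rose. The direction was opposite to the hypothesis, but the difference did not pass, and with 6 genes the test could not decide.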
